A study of Mus musculus with 4 samples.

How the data were processed

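Polyadenylated RNA of lung epithelial cells from IL-33 transgenic and control mice was sequenced after extraction with a Qiagen RNeasy kit, per the labels' protocols. Per the submitters' processing notes, the tools were TopHat2 version 2, Bowtie version 1 and featureCounts version 1, and the builds named were mm10 and GRCm38, which are the same assembly. The annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here, so overlapping and antisense genes and near-identical paralogs may share reads. The authors deposited 1 table of 43346 genes with a whole-number count of reads per gene and sample, not normalized, and an RPKM value beside each count. Per the file headers the table also gives the Ensembl identifier, a gene name, coordinates and a coding length. The RPKM values deposited by the authors were scaled to totals larger than the gene counts, which made up 80.3% to 82.8% of them. They were used only to work out those totals. All mitochondrial genes were 0 in every library, so no mitochondrial share could be used as a sign of RNA quality. All count columns matched 1 sample each.

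Symbols were taken by Ensembl identifier from the GENCODE M21 gene names, which held 42462 of the 43346 identifiers. The table's own name was kept for the others. Of these genes 29887 had a count in any library. Library totals ran from 76120696 counts (B) to 87723745 (E). No pair of libraries agreed within sampling noise: the chi-square per gene was 19.5 or more for all pairs, the smallest being that of E and F.

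Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which left 20872, and scaled by TMM. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) of transgenic against control libraries with no covariate, 2 libraries per group and Benjamini-Hochberg adjustment at 0.05. Standard errors are the log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes. In a gene called separated, both libraries of 1 group lay above both of the other. Gene lists were tested with camera (limma 3.58.1) on the edgeR object at a preset correlation of 0.01, for lists with at least 5 tested members, and with an estimated correlation, fry and ranks as alternatives. Of the 38 lists, 19 were pathways and 19 cell type markers, all fixed before the data were examined, as were the design, the rule for named genes and most alternatives. Some genes stand in several lists, so their calls are not independent. Among them, Il33 is in the IL-1 family and alveolar type 2 lists, Il1r2 in the IL-1 family and neutrophil lists, and Retnla in the macrophage activation and club cell lists. S100a8 and S100a9 are in the neutrophil and monocyte chemoattractant and the neutrophil lists, and Ccl24 is in the macrophage activation and eosinophil chemoattractant lists.

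The genes named are Il33 and Il1rl1, 10 genes per direction, the leading members of each list described (2 to 4 with the smallest p) and 5 sex-linked genes. Of the leading members, 1 is not reported here. The 10 per direction were to be those with the largest log2 fold changes past an adjusted p of 0.05, with a group mean of at least 5 CPM and no overlap between the groups. None passed, so the genes with the smallest p that met the other criteria, predicted gene models left out, were taken. A few others (among them Asic2, Clca1, Ptprc, Pecam1, Epcam, Ccl2, Csf3, Gm26917, Tgfbi and those named only for a call with 1 library left out) were chosen after their values were seen.

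The alternatives were DESeq2 size factors or upper-quartile factors, library sizes without mitochondrial, haemoglobin, immunoglobulin and surfactant genes, no filter or a stricter one (1 CPM in 2 libraries and a total of 20), each library left out in turn, the quasi-likelihood fit without its legacy setting or with robust dispersions, DESeq2 1.42.0, limma-voom and a fold minimum of 1.5. Chosen after seeing the data were a term for libraries B and D against E and F, the Y-linked share as a covariate, X and Y genes left out, and Il33 left out of the lists.

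The fits were tested on simulated counts for all 20872 genes, drawn from these libraries' means with 200 genes changed up or down. In the same counts, lists of 20 members were shifted upward by 0.5 on the log2 scale or left unshifted. Changed genes and list members were drawn only from genes averaging at least 1 CPM. When the simulated libraries also held the difference of B and D from E and F, the test recovered 0% of genes changed 1.5-fold, 11.6% of those changed 2-fold, 84.4% changed 4-fold and 98.8% changed 16-fold. With the term for B and D against E and F in the fit, it recovered 62.4%, 94.8%, 100% and 100% on the same counts. Without that difference in the counts, the fit with no such term recovered 54%, 86.4%, 100% and 100%. The simulated B and D shared a mean for each gene apart from the changes, as did E and F. The real B and D lay apart on the first principal component (-53.4 and -4.19). Il33, 11.55-fold higher in the real transgenic libraries, missed the threshold with and without the term. Recovery in the real libraries may thus be lower than simulated. Lists of 20 members shifted by 0.5 on the log2 scale were called in 100 of 100 cases and unshifted lists in 0 of 100, with members simulated independently, so correlated members were not covered. Nor were scarce ones: the median member averaged 0.833 CPM in the real T cell list and 0.362 CPM in the natural killer cell list. Figures were drawn with matplotlib.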

Results

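Polyadenylated RNA of mouse lung epithelial cells was sequenced from animals that over-express IL-33 from a transgene and from controls. IL-33 is a cytokine of the IL-1 family that epithelial cells release on damage, and it acts through the receptor encoded by Il1rl1. The sample labels call the material epithelial cells, while the series title calls it lung tissue. There were 2 transgenic libraries, B (transgenic replicate 1) and E (transgenic replicate 2), and 2 control libraries, D (control replicate 1) and F (control replicate 2). The sample titles name a mouse in the singular, but the number of mice per library is not stated in the sources used here, so p-values measure the spread between these libraries. The gene counts summed to 76120696 in B, 87723745 in E, 80764860 in D and 85330145 in F, and between 25713 and 27150 genes had at least 1 count. Sftpc, the surfactant protein C gene of alveolar type 2 cells, took 3.61% of the counts in B, 3.0% in D, 2.21% in E and 2.0% in F. The question the design poses is which genes differ between IL-33 transgenic and control lungs.

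Il33 was far higher in both transgenic libraries. Il33 (ENSMUSG00000024810, chromosome 19, 29925114 to 29960718, GRCm38) stood at 1723 counts per 1000000 (CPM) in B and 874 CPM in E, against 117 CPM in D and 108 CPM in F. The group means were 1299 ± 600 CPM in transgenic and 112.5 ± 6.38 CPM in control libraries (SD, n = 2 each), an 11.6-fold difference (log2 fold change 3.53, SE 0.37). The ratio of a transgenic to a control library ranged from 7.48 (E over D) to 16 (B over F). The sample titles do not give the sequence of the transgene. Any of its reads that matched were counted with those of the endogenous gene under this gene. It missed the threshold in edgeR's quasi-likelihood test over 20872 genes (adjusted p = 1), while DESeq2 gave an adjusted p of 1.84e-27. Without library B the edgeR log2 fold change was 2.96 (adjusted p = 0.00359), and without library E it was 3.93 (adjusted p = 0.000668). Il1rl1 (ENSMUSG00000026069, chromosome 1, 40429570 to 40465415) was low in every library, at 1.51 CPM in B, 2.48 in E, 0.57 in D and 1.89 in F (log2 fold change 0.70, SE 0.61), and its direction turned with the Y-linked share of each library (below) as a covariate, an alternative added after the data were seen (-1.08).

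The sex-linked genes differed between libraries of 1 group. Xist, which is transcribed from the inactive X chromosome of females, stood at 698 CPM in B, 811 in E, 356 in F and 1.19 in D. The summed CPM of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y, relative to D, was 0.554% in B, 9.0% in E and 47.5% in F. Library B thus carried female and library D male RNA, and libraries E and F carried RNA of both sexes. Eif2s3y had 0 counts in B and 5926 in D. Since the Y-linked share was lower in both transgenic than in both control libraries, sex and genotype overlap in part in every comparison below.

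**Figure D1:**
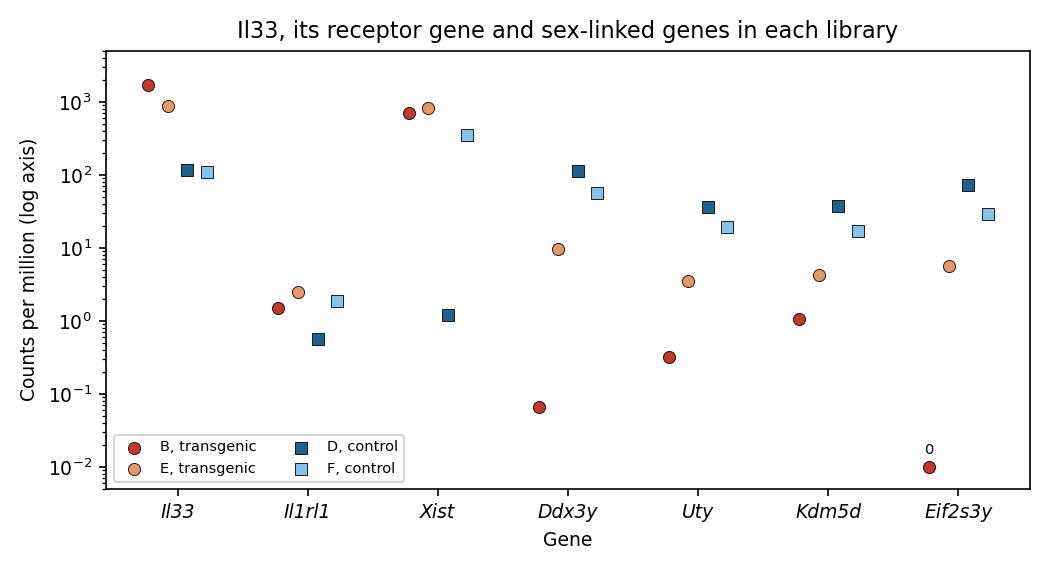
Counts per 1000000 (CPM, log axis) of Il33, Il1rl1, Xist and 4 Y-linked genes in each library, with circles for transgenic and squares for control libraries, 1 point per library; Eif2s3y in B, at 0 counts, is drawn at the bottom and marked 0. Il33 was 874 CPM or more in both transgenic libraries and 117 CPM or less in both controls, and Xist was 356 CPM in control library F but 1.19 in control library D.

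Across the genome the test called 0 genes higher and 0 lower at an adjusted p of 0.05 (edgeR quasi-likelihood, 20872 genes). At an unadjusted p under 0.05 there were 187 genes higher and 82 lower, 269 in all where chance alone would give 1044. DESeq2 called 1 gene, Il33, and limma-voom called 0. Both transgenic libraries lay above both controls for 2477 genes and below them for 2509, where chance gives 16.7% of genes, 3479, in each direction. The libraries did not vary mainly by genotype. On the first principal component, with 54.1% of the variance, B lay at -53.4 and D at -4.19, and E and F lay together at 27.0 and 30.6. Leaving out 1 library changed the counts: without E 3 were higher (Il33, Ephx4 and Egln1) and 12 lower, among the latter Ddx3y, Uty, Kdm5d and Eif2s3y. Without F there were 5 higher, namely Xist, its antisense partner Tsix and the predicted genes Gm26992, Gm27927 and Gm27733. Without B there were 2 higher, Il33 and Snx24, and without D there were 0.

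No gene besides Il33 passed by any of these tools on all 4 libraries, so the genes with the smallest p-values whose libraries did not overlap are given as values only. After Il33, those with higher values in transgenic libraries were Cytip (log2 fold change 0.57, SE 0.10), Ccr2 (0.98, SE 0.20), Slc26a4 (0.85, SE 0.20), Retnla (0.79, SE 0.18), Ighm (1.66, SE 0.40), Tlr4 (0.43, SE 0.11), Hc (0.52, SE 0.15), Aox3 (0.42, SE 0.12) and Lgals3 (0.44, SE 0.13). Ccr2 encodes the chemokine receptor of inflammatory monocytes, Slc26a4 the anion exchanger pendrin, Ighm the heavy chain of IgM, Tlr4 the receptor for lipopolysaccharide, Hc complement component C5 and Lgals3 galectin-3. Retnla, encoding the secreted protein RELMα, stood at 689 ± 73.1 CPM in transgenic and 398 ± 68.0 CPM in control libraries (SD, n = 2 each). Those with lower values were Apold1 (-0.87, SE 0.16), Csrnp1 (-0.48, SE 0.10), Kdm5d (-3.33, SE 0.75), Sertad1 (-0.51, SE 0.12), Arid5a (-0.59, SE 0.14), Egr3 (-1.12, SE 0.30), Uty (-3.82, SE 1.02), Nr4a1 (-0.47, SE 0.13), Nr4a2 (-0.50, SE 0.15) and Ier5l (-0.51, SE 0.16). Egr3, Nr4a1 and Nr4a2 are transcription factors induced within minutes of many stimuli, and Kdm5d and Uty lie on the Y chromosome.

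Gene lists fixed in advance were then tested as groups, each against all other genes tested, with camera at a preset correlation of 0.01 between genes. Of 38 lists, 15 were called higher and 6 lower in transgenic libraries at an adjusted p of 0.05, and 17 were not called. With a correlation estimated per list 0 were called, the smallest adjusted p being 0.422. The directional fry test called 0 as well (smallest adjusted p 0.0517, for T cells), and its mixed test called the T cell list (adjusted p = 0.0176) and the dendritic cell list (0.041). Over all genes tested, 0 members of any list passed. For 6 of the 15 lists called higher and 3 of the 6 called lower, the list medians of the 2 transgenic libraries did not overlap those of the 2 controls.

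Leukocyte markers made up 7 of the 15 lists called higher. Of 20 T cell genes, 18 had a log2 fold change above 0 (median 0.58), and 11 lay higher in both transgenic than in both control libraries (camera adjusted p = 1.46e-15, adjusted p = 0.422 with an estimated correlation). Adjusted over the list alone, 2 were higher: Cd3g, a chain of the T cell receptor complex (1.51 ± 0.14 CPM in transgenic and 0.446 ± 0.00044 CPM in control libraries, SD, n = 2 each), and the co-stimulatory receptor gene Cd28 (2.46 ± 0.17 and 1.04 ± 0.01 CPM). Cd8b1 and Themis had log2 fold changes of 1.36 (SE 0.51) and 0.99 (SE 0.38). Of 16 neutrophil genes, 14 had values above 0 (median 0.95) and 11 were separated (camera adjusted p = 2.45e-20, adjusted p = 0.422 with an estimated correlation). Of the 16, 6 were higher when adjusted over the list alone, including the collagenase gene Mmp8 (log2 fold change 1.49, SE 0.30), the decoy receptor gene Il1r2 (1.31, SE 0.27), the G-CSF receptor gene Csf3r (1.21, SE 0.27) and the granule protein gene Ngp (1.98, SE 0.44). All 10 natural killer cell genes tested had values above 0 (median 0.85), led by Il2rb (0.63, SE 0.24) and the granzyme gene Gzma (1.18, SE 0.53; camera adjusted p = 9.46e-07, adjusted p = 0.422 with an estimated correlation). Of 19 monocyte and interstitial macrophage genes, 15 had values above 0 (median 0.56), led by Ccr2 and the fractalkine receptor gene Cx3cr1 (0.94, SE 0.23; camera adjusted p = 2.84e-10, adjusted p = 0.422 with an estimated correlation). This last call was lost without library E (adjusted p = 0.0728). No natural killer cell or monocyte gene passed adjusted over the list alone (0 in each). Most of these markers were scarce: the median member averaged 0.833 CPM for T cells, 0.362 for natural killer cells, 1.80 for neutrophils and 4.17 for monocytes, and Ptprc, the gene of the pan-leukocyte antigen CD45, stood at 20.6 CPM in B, 30 in E, 8.21 in D and 16.5 in F.

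Markers of alveolar macrophages, B cells and innate lymphoid cells were called higher too. Of 18 alveolar macrophage genes, 16 had values above 0 (median 0.69), led by Pparg (0.60, SE 0.22) and the ribonuclease gene Ear2 (1.23, SE 0.51, but -0.19 with the Y-linked share as a covariate). The camera adjusted p was 2.79e-06, and 0.542 with an estimated correlation. The call was lost without library D (adjusted p = 0.591) or E (0.346) and turned to lower with the Y-linked share as a covariate (1.44e-05). Of 14 B and plasma cell genes, 11 had values above 0 (median 0.46), led by the immunoglobulin genes Ighm and Igkc (2.01, SE 0.67, but -0.255 with the same covariate). The camera adjusted p was 5.63e-05, and 0.422 with an estimated correlation, and the direction of the list turned with that covariate (adjusted p = 0.11). For group 2 innate lymphoid cells, which respond to IL-33, 15 of 20 genes had values above 0 (median 0.12), led by Il7r (0.94, SE 0.39) and Ltb4r1 (0.66, SE 0.30; camera adjusted p = 0.00306, adjusted p = 0.572 with an estimated correlation). That call was lost without D (adjusted p = 0.827) or E (0.351), and the direction turned with the covariate (0.0579). In these 3 lists 0 genes passed adjusted over the list alone.

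**Figure D2:**
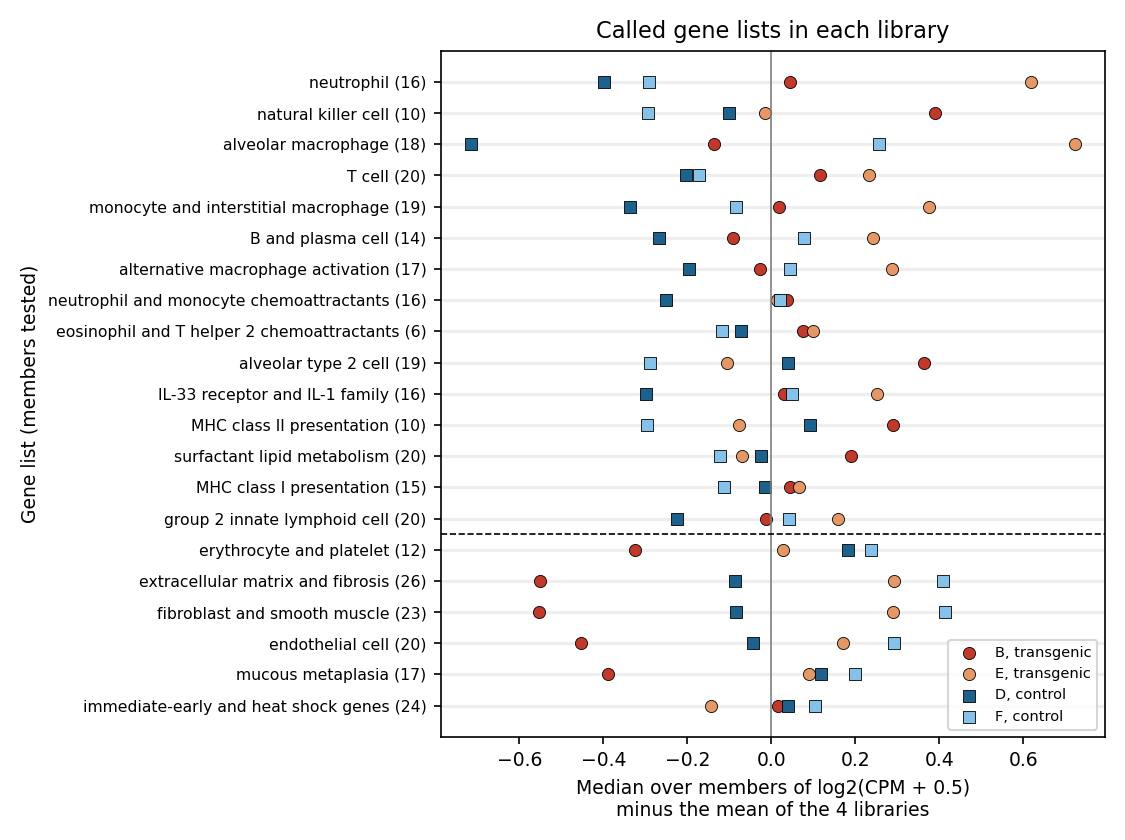
Median over the members of each called list of log2(CPM + 0.5) minus that gene's mean over the 4 libraries, with 1 point per library, circles for transgenic and squares for control libraries, and the number of members tested in brackets. Lists above the dashed line were called higher (15) and those below it lower (6); the T cell, natural killer cell, neutrophil and monocyte medians of B and E lay above those of D and F, while B alone lay far below the other libraries for the endothelial, fibroblast and matrix lists.

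Of the lists for IL-33 signalling, type 2 inflammation and chemoattractants, 4 were called higher. In the IL-33 receptor and IL-1 family list, 15 of 16 genes had values above 0 (median 0.25; camera adjusted p = 7.79e-11, adjusted p = 0.422 with an estimated correlation). The genes higher adjusted over the list alone were 2, Il33 itself and Il1r2. With Il33 left out of the lists, all 15 higher calls held at the preset correlation, this one among them. Genes of alternative macrophage activation, the macrophage state driven by IL-4 and IL-13, had 13 of 17 values above 0 (median 0.43). They were led by Retnla, which is also in the club cell list and need not come from macrophages, and the transcription factor gene Irf4 (0.90, SE 0.25). The camera adjusted p was 6.24e-07, and 0.422 with an estimated correlation. This call was lost without library E (adjusted p = 0.415). Both lists turned in direction with the Y-linked share as a covariate (adjusted p = 0.76 for each). Of the neutrophil and monocyte chemoattractants, 11 of 16 had values above 0 (median 0.38, camera adjusted p = 0.0216, adjusted p = 0.422 with an estimated correlation). They were led by the calprotectin genes S100a8 (1.28, SE 0.32) and S100a9 (1.26, SE 0.44), which are also in the neutrophil list. The next by p, the scarce Ccl2 (-0.74, SE 0.38) and Csf3 (-1.30, SE 0.73), lay lower in both transgenic libraries than in both controls. In this list 2 genes were separated higher and 2 lower. The call was lost without D or E and with camera on ranks (adjusted p = 0.0948), and its direction turned with the covariate (0.458). Eosinophil and T helper 2 chemoattractants had only 6 genes tested, 4 of them above 0 (median 0.31), led by Ccl24 (0.145 ± 0.018 against 0.0483 ± 0.0019 CPM, SD, n = 2 each) and Ccl5 (log2 fold change 1.27, SE 0.57; camera adjusted p = 0.0216, adjusted p = 0.422 with an estimated correlation). Without any 1 of the libraries that call was lost (adjusted p from 0.0702 to 0.72), and without E or F its direction turned. The type 2 cytokines and their receptors were not called (median 0.02, 10 of 18 above 0, adjusted p = 0.599), with log2 fold changes of 0.39 (SE 0.19) for Csf2 and 0.94 (SE 0.49) for Il5. Nor were the eosinophil markers (median 0.21, 5 of 9 above 0, adjusted p = 0.219) or those of mast cells and basophils (median -0.07, 4 of 12 above 0, adjusted p = 0.631, although the test ran toward higher). Adjusted over the list alone, 0 genes passed in any of these lists but the first.

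The mucous metaplasia list, which holds genes of mucus-secreting airway cells, was called lower. Of 17 genes, 4 had values above 0 (median -0.22; camera adjusted p = 0.00602, adjusted p = 0.464 with an estimated correlation), and 0 passed adjusted over the list alone. Its leading members went apart: Slc26a4 stood at 63.8 ± 13.8 CPM in transgenic and 35.3 ± 5.30 CPM in control libraries, while Fcgbp, encoding a mucus-associated protein, stood at 11.5 ± 5.37 and 21.3 ± 1.38 CPM (SD, n = 2 each). The call rested on library B, without which the direction turned (adjusted p = 0.773), and it was lost with the Y-linked share as a covariate (0.333). Clca1, named after its values were seen, was 16.8 CPM in B but 113 in E, 79.7 in D and 130 in F.

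The alveolar type 2 cell, surfactant lipid and antigen presentation lists were called higher, although the list medians of the groups overlapped in all but MHC class I. Of 19 type 2 cell genes, which include Il33, 18 had values above 0 (median 0.25), led after Il33 by Hc at 339 ± 49.8 against 236 ± 7.70 CPM (SD, n = 2 each; camera adjusted p = 2.50e-11, adjusted p = 0.524 with an estimated correlation). Only 2 of the 19 were separated between the groups, and adjusted over the list alone 1 passed, Il33. The camera call at the preset correlation held with Il33 left out. All 20 surfactant lipid genes had values above 0 (median 0.17), led by Acoxl (0.31, SE 0.10) and the acetyl-CoA carboxylase gene Acaca (0.22, SE 0.11; camera adjusted p = 3.74e-05, adjusted p = 0.542 with an estimated correlation), and the call was lost without library B (adjusted p = 0.343). All 10 MHC class II genes tested had values above 0 (median 0.25), led by the cathepsin S gene Ctss (0.98, SE 0.50, but -0.41 with the Y-linked share as a covariate) and H2-Eb1 (0.36, SE 0.23; camera adjusted p = 5.18e-05, adjusted p = 0.505 with an estimated correlation). Of 15 MHC class I genes, 10 had values above 0 (median 0.12) and 7 were separated, led by H2-Q7 (0.62, SE 0.20), whose reads may be shared with near-identical paralogs, and the class I transactivator gene Nlrc5 (0.62, SE 0.21; camera adjusted p = 0.00149, adjusted p = 0.422 with an estimated correlation). That call was lost without E (adjusted p = 0.0937) or F (0.227). Among surfactant lipid and MHC genes, 0 passed adjusted over the list alone.

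The vascular, stromal, red cell and immediate-early lists were called lower, although for the endothelial, fibroblast and matrix lists the median of transgenic library E lay above that of control library D. The endothelial list had 0 of 20 values above 0 (median -0.24), led by Lyve1 (-0.26, SE 0.14) and Egfl7 (-0.33, SE 0.21; camera adjusted p = 1.23e-06, adjusted p = 0.593 with an estimated correlation). Fibroblast and smooth muscle genes had 1 of 23 above 0 (median -0.25), led by Tcf21 (-0.40, SE 0.29) and Cnn1 (-0.32, SE 0.26; camera adjusted p = 0.000148, adjusted p = 0.542 with an estimated correlation). Matrix and fibrosis genes had 3 of 26 above 0 (median -0.26), among them Mmp14 (-0.27, SE 0.17; camera adjusted p = 6.04e-05, adjusted p = 0.654 with an estimated correlation). Without library B all 3 turned in direction, at adjusted p 0.704, 0.552 and 0.0154, and without F the endothelial and matrix calls were lost (0.158 and 0.476). Erythrocyte and platelet genes had 0 of 12 above 0 (median -0.55), led by Slc4a1 (-1.96, SE 0.60) and Hba-a2 (-1.05, SE 0.53, but 1.04 with the Y-linked share as a covariate). The camera adjusted p was 5.18e-05, and 0.422 with an estimated correlation, and the call was lost with the same covariate (0.655). Of 24 immediate-early and heat shock genes, 1 had a value above 0 (median -0.14) and 10 lay lower in both transgenic libraries, led by Egr3 at 4.85 ± 1.72 against 10.5 ± 1.85 CPM and Nr4a1 at 271 ± 22.5 against 374 ± 24 CPM (SD, n = 2 each; camera adjusted p = 9.46e-07, adjusted p = 0.464 with an estimated correlation). Without library E this call was lost (adjusted p = 0.279). In each of these 5 lists 0 genes passed adjusted over the list alone. Endothelial transcripts were abundant in every library for a preparation labelled epithelial: Pecam1 stood at 824 CPM in B, 1250 in E, 1000 in D and 1330 in F, and the epithelial adhesion gene Epcam at 164, 115, 148 and 110 CPM.

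The remaining lists were not called by camera at the preset correlation, and in each 0 members passed adjusted over the list alone. Their median log2 fold changes were 0.06 for cholesterol synthesis (adjusted p = 0.0697), 0.13 for ciliated cells (0.0786), 0.19 for complement (0.23), 0.09 for epithelial junctions (0.339) and -0.07 for interferon-stimulated genes (0.52). They were -0.03 for tuft and neuroendocrine cells (adjusted p = 0.599), 0.01 for cell cycle genes (0.716), 0.06 for club cells (0.757), 0.07 for oxidative stress and xenobiotic enzymes (0.813) and -0.003 for NF-kappaB targets (0.822). Dendritic cell genes had a median of -0.10 although the test ran toward higher (adjusted p = 0.219), with Irf8 at 0.56 (SE 0.19) and Itgae at 0.71 (SE 0.26). Basal cell genes likewise had a median of -0.03 with the test toward higher (0.861), and endoplasmic reticulum stress and alveolar type 1 genes had medians of 0.0002 and 0.01 with the test toward lower (0.757 for each). Among club cell genes, Retnla and Scgb3a1 led, the latter at 4.05 ± 3.44 CPM in transgenic and 13.1 ± 1.58 CPM in control libraries (SD, n = 2 each); without E it passed edgeR's test (log2 fold change -3.03, adjusted p = 0.0143). With 2 libraries per group, an exact two-sided permutation test cannot go below p = 0.333.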

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

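The term for B and D against E and F, the Y-linked share, the X and Y genes left out and Il33 left out of the lists were chosen after the results were seen, and the other alternatives before. The count of 0 genes higher and 0 lower held under every normalization, filter and dispersion setting tried, limma-voom (286 genes at an unadjusted p under 0.05), a fold minimum and the 3 later alternatives that test genes, but DESeq2 called 1 gene higher, Il33 (log2 fold change 3.53, adjusted p = 1.84e-27); the cause was not tested. With 1 library left out, where the lone library is assumed to vary like the other group, 0 to 5 genes were higher and 0 to 12 lower, and the log2 fold change of Il33 ranged from 2.96 to 3.93, past the threshold without B or E; the cause was not tested. The term for B and D against E and F left 0 genes called, with 1281 at an unadjusted p under 0.05 in place of 269 and an adjusted p of 0.252 for Il33, which ranged over its alternatives from 1.84e-27 to 1. The labels do not pair libraries across groups, so this term follows a grouping seen in the data and is not a paired design; with it 16 lists were higher and 6 lower.

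The 15 lists higher and 6 lower became 0 and 0 with an estimated correlation, and 0 and 0 by fry. That correlation was 0.948 for endothelial, 0.904 for alveolar type 2 and 0.526 for neutrophil genes, against the preset 0.01. Where members are that correlated, the p-values at the preset correlation are too small. It was -0.0526 for T cell and -0.00364 for MHC class I genes, and those calls were lost too. For these lists the estimate lay below the preset value, so correlated members cannot account for their losses. With an estimated correlation camera also takes its degrees of freedom from the 4 libraries and not from the number of genes. The losses thus do not measure correlation alone, and the share of each was not tested. With the preset correlation the counts stayed within 1.5 times (11 to 17 higher and 5 to 8 lower with 1 library left out), but the lists behind them changed: of the 15 higher and 6 lower calls, 13 and 2 were kept without B, 11 and 6 without D, 8 and 5 without E, 13 and 4 without F, and 9 and 4 with the Y-linked share. The neutrophil, T cell, MHC class II and alveolar type 2 lists kept their calls in every such alternative run. The natural killer cell list kept its call wherever tested. With 1 library left out, adjusted p ranged from 9.27e-11 to 0.773 for mucous metaplasia, 6.76e-17 to 0.476 for matrix and fibrosis, 1.18e-12 to 0.704 for endothelial cells, 6.24e-11 to 0.552 for fibroblasts and smooth muscle (the first 4 reversed without B) and 0.0702 to 0.72 for eosinophil and T helper 2 chemoattractants (reversed without E or F). The matrix list was called higher without B (0.0154). With the Y-linked share, the direction reversed for the IL-33 receptor and IL-1 family (adjusted p = 0.76), alternative macrophage activation (0.76), neutrophil and monocyte chemoattractants (0.458), alveolar macrophages (1.44e-05), group 2 innate lymphoid cells (0.0579) and B and plasma cells (0.11). The mucous metaplasia (0.333) and erythrocyte and platelet calls (0.655) were lost. The log2 fold changes of 6 of the 65 genes taken by the naming rule reversed: Il1rl1 (-1.08), Xist (-5.11), Ctss (-0.41), Ear2 (-0.19), Igkc (-0.26) and Hba-a2 (1.04). The cause was not tested. Within a group, that share differed most between D (100%) and F (47.5%), so its slope rested mainly on them. The slope was carried over to B (0.554%) and E (9.0%). With 4 libraries this fit left almost no residual freedom, and these reversals cannot tell sex from genotype. Low counts, often 1 CPM or less, may limit leukocyte lists. The stricter filter kept 12 higher calls, lost 0 and left B and natural killer cells out. In the simulation with the difference of B and D from E and F, the test recovered 0% of 1.5-fold changes in genes averaging at least 1 CPM. With the term for that difference in the fit it recovered 62.4%. The simulated B and D shared a mean, however, while the real ones lay apart.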

Other observations

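All tests of explanations in this part were chosen after the results were seen. The gene Asic2, encoding an acid-sensing ion channel of neurons (chromosome 11, 80880169 to 81968457), parted the libraries against genotype: it stood at 106 CPM in B and 111 CPM in D, but at 0.158 CPM in E and 0.376 CPM in F (7975, 8956, 14 and 32 counts). It was the single gene called when B and D were set against E and F, and the single one at least 10-fold apart at 5 CPM or more. The neighbouring genes Rhot1 (74.1, 71.8, 74.1 and 72.5 CPM in B, D, E and F) and Myo1d (187, 169, 171 and 164 CPM) lay close together in all 4 libraries. Other genes parted B and D from E and F by less. Gm26917 stood at 368 CPM in B and 459 in D, but 74.3 in E and 89.9 in F, and Tgfbi at 51.8 and 64.2, but 158 and 162. Several imprinted growth genes, which are high in fetal and young lung and fall with age, were well expressed in every library: H19 stood at 292 to 415 CPM, Mest at 475 to 704 CPM and Igf2 at 86.2 to 133 CPM, and the proliferation marker Mki67 at 127 to 153 CPM. The imprinted genes Zim1 (0.5692 to 1.949 CPM) and Plag1 (1.538 to 2.065 CPM) were scarce. Elastin (Eln) took 3950 CPM in B, 6390 in D, 7220 in E and 9510 in F.

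Of the 7 leukocyte lists called higher, the medians of T cell, natural killer cell, neutrophil and monocyte markers were higher in both transgenic libraries than in both controls. A lower share of epithelial cells in the transgenic preparations would raise markers of every other cell type alike, yet the median log2 fold change of the 115 members of the 7 lists exceeded that of 43 endothelial and fibroblast genes by 0.826 (bootstrap interval 0.646 to 0.958 over members, not mice), and by at least 0.66 with any 1 library left out (0.472 to 0.814 without B). More blood would bring its red cells and platelets along, yet the 115 members exceeded 12 erythrocyte and platelet genes by 1.13 (0.725 to 1.5), and by at least 0.877 with any 1 library left out (0.229 to 1.12 without D). The 7 lists were taken because they were called higher; over all 10 leukocyte lists (145 members) the median was lower, at 0.429, and 0.153 without E, but the lower bounds of both differences stayed above 0 with all libraries (0.532 and 0.605) and without any 1 of them (0.422 and 0.194 at the least). The parts of the erythrocyte and platelet list moved apart, however: the median of 4 haemoglobin genes was -0.896, but 0.0615 without D, and that of 5 platelet genes was -0.264, but 0.646 without F. The comparison lists had all been called lower, so differences above 0 in part restate those calls. The intervals take members as independent, although the estimated correlation was 0.948 for endothelial genes, so they may be too narrow. At most, the values argue against whole blood and not against leukocytes of blood alone. Sex composition stayed open. If log2 differences scaled with the Y-linked share, it would make the difference of E from F 0.387 times that of B from D. The 115 members exceeded this by a median of 0.184 (0.128 to 0.268, and 0.15 over the 145). The lists went apart, from -0.0249 for group 2 innate lymphoid cells to 0.685 for neutrophils, with intervals above 0 in 3 of the 7. With the Y-linked share as a covariate 4 calls held and 3 lists turned in direction. The scaling is doubtful, since shares of mixed RNA add on the linear and not the log2 scale. Xist differed by 9.08 between B and D but by 1.19 between E and F. Ddx3y (-9.40 and -2.53) and Eif2s3y (-9.52 and -2.37) also fell short, while Uty (-6.42 and -2.41) and Kdm5d (-5.02 and -1.95) kept near it. The excess thus cannot decide on sex. With sex open, a rise of these cells in the lungs of transgenic mice is a hypothesis that these libraries cannot settle.

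The libraries parted more along other lines than by genotype. Of the 3 ways to split the 4 libraries into pairs, genotype gave 269 genes at an unadjusted p under 0.05, B and D against E and F gave 4067, the highest of the others, and all 3 gave at least as many as genotype; 3 splits are too few for a share under 0.05. B and D did not form a pair as close as E and F, however: E and F correlated at 0.9937, while D correlated at 0.988 with E and 0.9888 with F but at 0.9859 with B, and on the first principal component D (-4.19) lay nearer E (27.0) and F (30.6) than B (-53.4). The measures went apart, since by chi-square per gene D lay nearer B (62.55) than E (75.99) or F (81.97). B also correlated less with E (0.9836) and F (0.9825) than with D. Coding length and transcript GC argue against a length or composition bias as the main source of the split with 4067 genes, since the larger squared rank correlation over genes with the difference between the pairs was 0.026. Age stayed open: of 16 imprinted growth genes, 3 were higher in B and D by 0.2 or more on the log2 scale (Dlk1, Meg3 and Rian, which form 1 locus) and 5 were lower, from 4 loci. A difference in litter, dissection or preparation day between the pairs could not be tested here.

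Libraries E and F carried RNA of both sexes. If the female RNA of control library F came from a transgenic library, F would need at least 384 CPM of Il33, and it held 108 CPM, below the 117 CPM of D. If the male RNA of E and F came from library D, Asic2 would reach 10 CPM in E and 52.8 CPM in F, and the larger ratio of observed to expected was 0.016. These values argue against transgenic RNA in F and against RNA of D in E and F, while RNA of F in E was not tested. The reading for D holds only if Asic2 was part of its RNA before the library was prepared, which is not known. Pools of male and female mice, although the sample titles say mouse in the singular, or RNA of mice outside this series, stay open, and pooled mice might account for it without any error of handling.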
